A study of Mus musculus with 7 samples.

How the data were processed

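The series holds RNA sequencing of mouse CD150-negative cells, with a cell type of HSC (haematopoietic stem cell) in the labels, from 4 wild-type (WT) samples and 3 samples that carry a deletion in band 5G2 of chromosome 5 (5G2del), all of strain C57/B6. CD150 is the surface protein encoded by Slamf1, and the labels name no other marker of the sort. Per the labels' protocols, RNA was taken up in Trizol, purified with a column kit, amplified with the Ovation RNA-Seq System V2 and sequenced as paired ends on a NovaSeq instrument. Whether libraries of a group came from separate animals is not given in the sources used here, so the p-values measure the spread between these libraries, part of which may be technical. The length, ends and zygosity of the deletion are likewise not given.

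The values used are log2 CPM, log2 counts scaled to library size, for 16760 genes, deposited by the authors in 1 results table together with their own log2 fold change, moderated t score, p-value and q-value for each gene. Per the submitters' processing notes, STAR 2.7.9a, RSEM 1.3.0 and limma 3.50.3 were used, and the genome builds mm10 and GRCh38 were named without a role. The gene annotation, the filter on low genes and the scaling method are not given in the sources used here. The gene set had been filtered before deposit, so genes below the authors' filter were not analysed here. In each column the deposited log2 CPM steps back to expected counts of 2 decimals, on an offset of 0.5 count, and 70.8% of those expected counts were whole within 0.01. A voom fit rebuilt from these counts gave back the authors' deposited log2 fold changes to within 4.49e-14 and their t scores to within 1.21e-13. The expected counts were used for depth, for counting floors and for that rebuilt fit. They were not whole reads, so no count model was used. RSEM divides reads among similar genes, and strand is not stated, so values of paralogs, of overlapping genes and of antisense partners are uncertain.

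The columns of the table show the group of a library but not which sample it is. Libraries are therefore named by group and letter, 5G2del-A to 5G2del-C and WT-A to WT-D, with no tie made to the sample numbers. The serial numbers in the column names run in the same order of groups as the deposited samples, but order alone was not taken as a tie. Expected counts of the listed genes summed to between 37930174 and 52194274 per library, and the library sizes behind the CPM ran from 34865420 to 55716549. A floor of 3 counts corresponded to between 0.0538 and 0.0860 CPM. The floor covers counting error alone, because amplified reads without molecular identifiers are not independent molecules. No library pair differed by as little as sampling noise (chi-square per degree of freedom of at least 77.1), so none was a copy of another. Repeat amplifications of the same RNA may also exceed that noise, so technical repeats could not be told apart this way. All 7 libraries were counted as separate. Gene positions and classes came from the GENCODE M21 annotation of mm10 by gene identifier, which matched all but 12 of the 16760 genes. Symbols are those of the deposited table, of which 147 differ from that annotation and 15 occur more than once.

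Before the data were examined, the comparison, its threshold, 29 gene lists, the rule for named genes and a set of alternatives were fixed. The comparison of 5G2del with WT used limma 3.58.1 in R 4.3.3 with a trend in the prior variance (limma-trend) on the deposited log2 CPM, with all 7 libraries, no covariate and a Benjamini-Hochberg adjusted p under 0.05. Fold changes are 5G2del over WT, so positive values are higher in 5G2del. Those of genes near 0 counts depend on the 0.5 offset and carry no bound. Lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry. Single values and list means were compared by two-sided exact permutation over the 35 ways to split 7 libraries into 3 and 4, which can give a p of 0.0286 at the smallest. On simulated data with known changes, limma-trend found 12.0% of genes changed by 1 on the log2 scale and 45.0% of those changed by 2, among 16760 genes; for genes with a mean log2 CPM over 2, the shares were 20.0% and 71.9%. It made 11 false calls over 5 simulations. An interval list with 27 members lowered by 1 on the log2 scale was found by camera in 20 of 20 simulations and by permutation in 15. The 27 were the first members in the deposited order, which follows the authors' p-value. Members with a small spread may thus be over-represented among them, and these 2 rates may be too high. Camera made 1 call over all lists with no change. The simulations drew each gene independently. In the real libraries the estimated correlation was 0.074 for the interval list and 0.42 for the interferon list. These rates therefore do not carry over to lists with correlated members.

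The lists covered the 5G2 interval and the 5A3 interval, the latter holding other mouse orthologues of human band 7q22. They covered HSC genes, lymphoid priming genes, myeloid progenitor genes, mature neutrophil and monocyte genes, megakaryocyte and platelet genes, erythroid genes, B lineage markers, T and NK markers, mast cell and basophil markers, macrophage and dendritic cell markers, and stromal and endothelial markers. They also covered S phase genes, G2/M phase genes, oxidative phosphorylation subunits, interferon response genes, NF-kB and inflammation genes, immediate early genes, p53 target genes, DNA damage signalling and repair genes, Ras-ERK feedback and output genes, PI3K-AKT-FOXO genes, cholesterol synthesis genes, glycolysis and hypoxia genes, unfolded protein response genes, sex-linked genes, ribosomal protein genes and mitochondrially encoded genes. The 5G2 interval list was drawn from the known gene order of 7q22.1, and 1 member, Naa80, lies on chromosome 9. Nampt of the 5A3 interval list lies on chromosome 12. The rule for named genes took interval members past the threshold and Cux1; the 10 genes most raised and the 10 most lowered among those past the threshold with groups that did not overlap; up to 4 members with the smallest p of each list with a passing set test or a member past the threshold; up to 2 of other lists; and Slamf1, Kit, Ly6a, Cd48, Cd34, Flt3, Procr and Cux1. Some genes that the rule took are not reported here. Genes named outside this rule were chosen after their values were seen and are marked so.

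Fixed alternatives left out each library in turn, dropped the trend, used quantile normalization, kept only the genes above the median of mean expression or only protein-coding genes, removed the interval list, moved the threshold, changed the background of the interval test, changed the set test and left out genes held by more than 1 list. Chosen after the data were seen were the authors' voom fit, array weights, rescaling to equal totals, Fisher's exact test at an unadjusted p, the run of genes from Rasa4 to Zan, permutation of list medians, the removal of low list members and the removal of both libraries rich in neutrophil transcripts.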

Results

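Gene expression was measured by RNA sequencing in CD150-negative mouse cells labelled as HSCs, in 4 WT libraries and 3 libraries with a deletion in chromosome band 5G2, the mouse counterpart of part of human band 7q22. Loss of 7q22 material is a recurrent event in myeloid malignancies, and the series addresses it with a mouse deletion. Expected counts over the 16760 listed genes summed to 44957266 ± 6261151 per WT library (SD, n = 4) and 41970821 ± 4945579 per 5G2del library (SD, n = 3). The genes of the 2 mitochondrial ribosomal RNAs took 29.4% ± 3.86 of these counts in WT and 24.8% ± 2.60 in 5G2del (exact permutation p = 0.171). Pearson correlations between libraries, across genes, ran from 0.846 to 0.926. WT-B stood apart, with 1104 genes at 0 counts against 83 to 492 in the other libraries, and the first principal component, with 36.3% of the variance, separated it from the rest.

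The deletion was first examined at the genes of band 5G2. Cux1, a homeobox transcription factor of 7q22, was at 7.29 ± 0.64 log2 CPM in 5G2del (SD, n = 3) and 8.41 ± 0.18 in WT (SD, n = 4), a log2 fold change of -1.12 ± 0.25 (SE). Trim56, a ubiquitin ligase of innate immune signalling, was at 4.88 ± 0.33 against 5.93 ± 0.14, a log2 fold change of -1.05 ± 0.19. Fis1, an adaptor of mitochondrial fission, and Lrwd1, a binding partner of the origin recognition complex, had log2 fold changes of -0.89 ± 0.24 and -0.90 ± 0.26. For these 4 genes, which the fixed rule named, every 5G2del library lay below every WT library. Cux1 measured 7.06, 6.80 and 8.01 log2 CPM in 5G2del-A, 5G2del-B and 5G2del-C, and 8.17 to 8.59 in the WT libraries.

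Of the 75 listed genes of the 5G2 interval, 53 were measured, of which 37 were lower and 16 higher in 5G2del, with a median log2 fold change of -0.28. The list as fixed holds 1 gene from elsewhere, Naa80 on chromosome 9, which is counted among the 53 here and below. In limma-trend 0 members passed adjusted p 0.05 over all genes, 11 had an unadjusted p under 0.05, 9 of them lower, and the authors' deposited table likewise held 0 calls. Adjusted over the list alone, 2 members passed and fell, Trim56 (limma adjusted p = 0.00968) and Cux1 (limma adjusted p = 0.0267). With 1 library left out between 1 and 3 members passed, and without the trend 0 did. Members lower at an unadjusted p under 0.05 numbered 9 of 53 in the list and 366 of 16707 among the other genes, or 2.19% (Fisher's exact test, two-sided, p = 2.37e-06), and 26 of 1123 among the other genes of chromosome 5 (p = 1.10e-05). Camera from limma put the list below other genes (adjusted p = 1.13e-05), with adjusted p = 0.660 with an estimated correlation. Exact permutation of the list's mean gave p = 0.143. That of its median, chosen after the data were seen, gave p = 0.0857, and with quantile normalization the median passed (exact p = 0.0286).

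Over 9332 runs of 20 neighbouring expressed genes, the strongest lay on chromosome 5, from Mdh2 to Slc12a9, with a mean log2 fold change of -0.65, and 1 of 35 splits of the libraries, the real one, gave a run as strong (highest other 0.60). A stretch of mm10 chromosome 5 overlapping it was then marked off after the values were seen, with its ends set from the fold changes, so the counts inside it and the contrast with its neighbours partly follow from that choice. All 28 measured genes from Rasa4 to Zan, between positions 136083916 and 137477064 (1.39 Mb), had lower means in 5G2del, with log2 fold changes from -2.81 for Muc3a to -0.28 for Trip6 and a median of -0.87, which is 0.547 of the WT level. The sign of Trip6 turned without 5G2del-A (0.19) and that of Zan without WT-B (0.0036). Their mean log2 CPM was 2.04 ± 0.24 in 5G2del (SD, n = 3) and 3.00 ± 0.07 in WT (SD, n = 4). For 9 of the 28 genes the groups did not overlap, and 12 had an unadjusted p under 0.05. Among the 23 protein-coding genes of the stretch, these counts were 6 and 9. Other members with an unadjusted p under 0.05 were Myl10 (-2.03 ± 0.59), Ift22 (-0.97 ± 0.36), Orai2, a calcium channel subunit (-0.65 ± 0.23), and Srrt (-0.51 ± 0.17). Myl10 was at 1.37 and 1.23 log2 CPM in 5G2del-A and 5G2del-B, but at 4.01 in 5G2del-C, above WT-A at 3.62. The transcripts A430110C17Rik (-1.72 ± 0.33) and Gm38082 (-1.27 ± 0.28) lie within Cux1 on its strand, so their reads cannot be told apart from Cux1 reads.

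Genes on either side had other values. Just before Rasa4, Ywhag had a log2 fold change of 0.00 ± 0.20 and Dtx2 of 0.10 ± 0.31, and just after Zan, Pop7 had 0.33 ± 0.29, Gigyf1 0.47 ± 0.31 and Gnb2 0.02 ± 0.21; these genes, too, were chosen by position after the values were seen. The signs of Ywhag, Dtx2 and Gnb2 turned in other settings, Gigyf1 was at 0.21 without 5G2del-A and 0.84 without 5G2del-C, and Pop7 at 0.53 without 5G2del-A, 0.20 without 5G2del-C and 0.13 without WT-A. The 20 expressed protein-coding genes before Rasa4 had a median of 0.04 and the 20 after Zan of -0.02. Of the 53 interval list members, the 22 inside the stretch were all lower (median -0.84) and the 31 outside had a median of 0.00. The 5A3 interval list, drawn up for other 7q22 genes on proximal chromosome 5, had 6 of 11 measured members lower and a median of -0.03. It did not pass (camera adjusted p = 0.912), and 0 members passed adjusted over the list alone. Its member Nampt, at -0.31 ± 0.20 (-0.18 without WT-C), lies on chromosome 12 and is counted in the list as fixed. Napepld was at 0.57 ± 0.43 (0.87 without 5G2del-B, 0.33 without 5G2del-C).

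**Figure D1:**
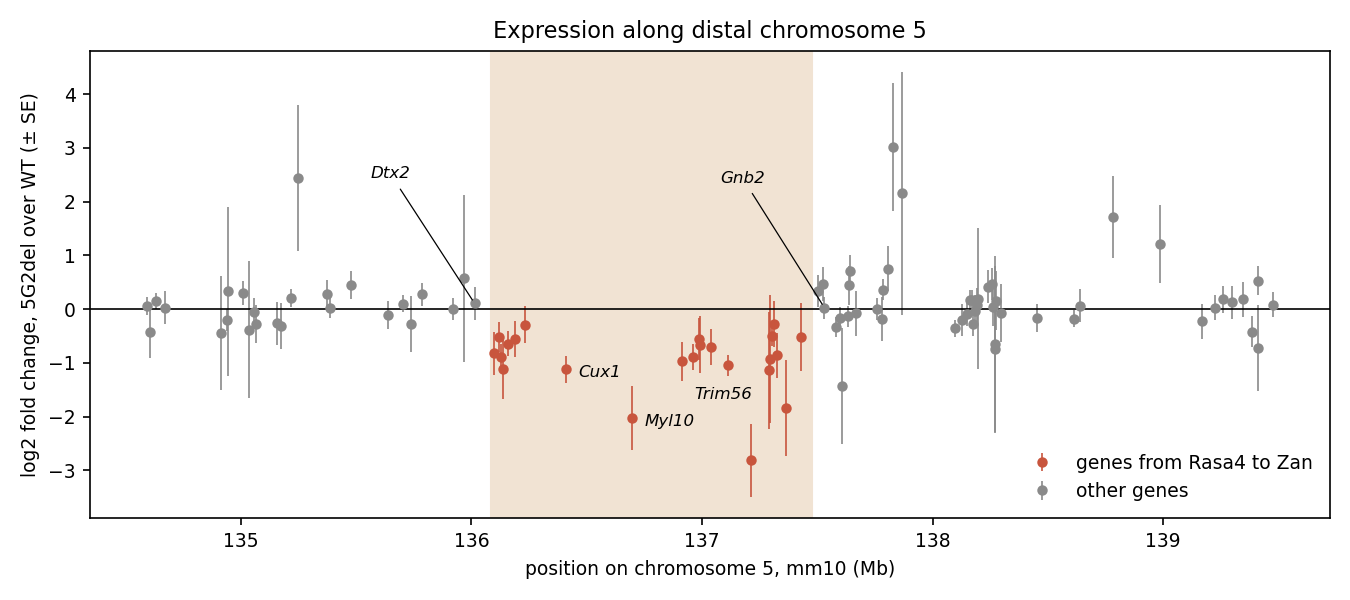
Log2 fold change of 5G2del over WT (± SE, 3 against 4 libraries) of protein-coding genes by position on mm10 chromosome 5 in Mb; red points in the shaded stretch are genes from Rasa4 to Zan and grey points other genes. All red points lie below 0, between -2.81 and -0.28.

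**Figure D2:**
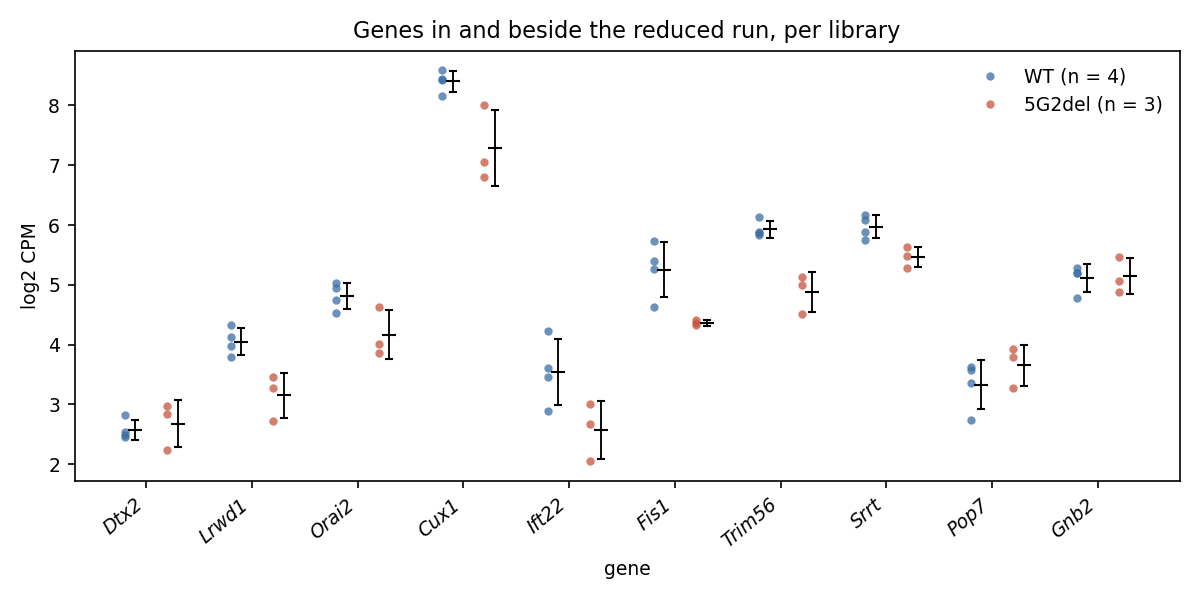
Log2 CPM per library of genes in and beside the stretch, in order of position (blue, WT, n = 4; red, 5G2del, n = 3; bars, mean ± SD). For Cux1, Trim56, Fis1, Lrwd1 and Srrt every 5G2del library lies below every WT library, and for Dtx2, Pop7 and Gnb2 the groups overlap.

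Across all genes, the comparison of 5G2del with WT asked which transcripts differed with the deletion. No single gene rose or fell past the threshold: limma-trend called 0 of 16760 genes, with the lowest adjusted p at 0.151, and 656 genes had an unadjusted p under 0.05 (281 higher, 375 lower; 838 expected by chance). The authors' deposited table held 0 genes past 0.05 (lowest adjusted p 0.990) and 625 with an unadjusted p under 0.05 (347 higher, 278 lower), and limma without the trend called 1, Sfrp5. Groups did not overlap for 956 genes, 5.70% of those tested, where chance gives 5.71%. The median residual SD was 0.32 on the log2 scale among the 10358 genes with a mean log2 CPM over 2.

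Of 7 surface markers used to define early blood progenitors, 6 overlapped between groups. Kit, the stem cell factor receptor, was at 8.20 ± 0.02 log2 CPM in 5G2del and 8.11 ± 0.10 in WT, and Cd34 at 8.30 ± 0.16 and 8.17 ± 0.21. Ly6a, which encodes Sca-1, had a log2 fold change of -0.42 ± 0.31, Flt3 of -0.20 ± 0.24 and Procr of 0.22 ± 0.20. Slamf1, the sort marker, was low in both groups, at 0.56 ± 0.14 log2 CPM in 5G2del (SD, n = 3) and -1.10 ± 0.98 in WT (SD, n = 4), a log2 fold change of 1.66 ± 0.75 without overlap of the groups (limma unadjusted p = 0.0504). Cd48, which marks progenitors downstream of the stem cell, had 0.99 ± 0.42 (limma unadjusted p = 0.0372). All 7 missed the adjusted threshold. With 1 library left out, Ly6a ran from -0.68 (5G2del-C or WT-A) to -0.19 (5G2del-A), Flt3 from -0.40 (WT-B) to -0.0016 (5G2del-B), Procr from 0.11 (WT-A) to 0.35 (WT-B), Cd34 from 0.033 (WT-B) to 0.20 (WT-C), and Kit was at 0.044 without WT-A and Cd48 at 0.64 without WT-B.

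Of 27 lists fixed in advance and tested with camera at the preset correlation, 9 passed adjusted p 0.05, 4 lower and 5 higher in 5G2del. With an estimated correlation 0 passed, with a smallest adjusted p of 0.660 for the interval, interferon and mitochondrially encoded lists, and fry called 0 lists in 1 direction and 1, the 5G2 interval, in either direction. Adjusted over the list alone, 0 genes passed in the lists below unless stated, and 0 over all genes. Of 108 genes examined with each library left out, 43 moved in log2 fold change by over 1.5 times, and values without the libraries that moved them most stand beside most of these genes.

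Interferon response genes lay lower in 5G2del in 39 of 44 members, 14 of them with an unadjusted p under 0.05, and had a median log2 fold change of -0.42 (camera adjusted p = 5.69e-15; adjusted p = 0.660 with an estimated correlation). Ifi44 had a log2 fold change of -1.11 ± 0.26, Cmpk2 of -0.89 ± 0.23, Oas3 of -0.76 ± 0.23 and Oas2, like Oas3 an antiviral oligoadenylate synthetase, of -1.13 ± 0.35, each without overlap of the groups. The list's mean log2 CPM was 4.17 ± 0.31 in 5G2del (SD, n = 3) and 4.62 ± 0.47 in WT (SD, n = 4). Exact permutation gave p = 0.257 for the list's mean and p = 0.171 for its median. The library values overlapped: WT-A and WT-B were at 4.35 and 4.10, 5G2del-C at 4.51, and WT-C and WT-D at 5.09 and 4.94. The 14 members at an unadjusted p under 0.05 came to between 5 and 19 with 1 library left out, the fewest without 5G2del-B, with 8 without 5G2del-A, 8 without WT-C and 7 without WT-D.

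Mitochondrially encoded genes were lower in 11 of 13 members (median -0.34; camera adjusted p = 5.85e-07; adjusted p = 0.660 with an estimated correlation; exact permutation p of the median 0.0857). The complex I genes mt-Nd4l (-0.59 ± 0.18), mt-Nd2 (-0.60 ± 0.20), mt-Nd6 (-0.58 ± 0.20) and mt-Nd5 (-0.40 ± 0.16) were among them. The nuclear oxidative phosphorylation subunits lay the other way, higher in 70 of 76 members (median 0.19; camera adjusted p = 2.30e-05; adjusted p = 0.797 with an estimated correlation), among them Uqcrc1 (0.33 ± 0.16), Atp5a1 (0.23 ± 0.13), Ndufa8 (0.40 ± 0.24) and Ndufb8 (0.42 ± 0.26). Their call was lost without WT-A (camera adjusted p = 0.904), where Ndufa8 was at 0.26 and Ndufb8 at 0.19. Whether the 2 groups of respiratory genes differed in direction was not tested.

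Ribosomal protein genes were higher in 81 of 81 members (median 0.25; camera adjusted p = 5.85e-07; adjusted p = 0.797 with an estimated correlation). Rpsa had a log2 fold change of 0.37 ± 0.19, Rps2 of 0.39 ± 0.21, Rpl8 of 0.32 ± 0.17 and Rpl18 of 0.33 ± 0.20. WT-A was lowest, with a list mean of 8.24 log2 CPM against 9.05 to 9.60 in the other libraries, and without WT-A the direction turned (camera adjusted p = 0.438), with Rps2 at 0.21 and Rpl18 at 0.18. Without 5G2del-C the call was lost (camera adjusted p = 0.205).

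Cell cycle genes were higher on balance. S phase genes were higher in 37 of 40 members (median 0.25; camera adjusted p = 1.94e-06; adjusted p = 0.796 with an estimated correlation), with Prim1, the DNA primase subunit, at 0.41 ± 0.17, Uhrf1 at 0.67 ± 0.28 and Hells at 0.43 ± 0.20. Exact permutation of the S phase median gave p = 0.257. The list means overlapped, with WT-A at 5.25 log2 CPM above 5G2del-A at 5.14 and 5G2del-C at 5.03, and WT-C lowest at 4.50. G2/M phase genes were higher in 43 of 56 members (median 0.17; camera adjusted p = 0.0226; adjusted p = 0.797 with an estimated correlation), with Cks1b at 0.54 ± 0.18, Cdk1 at 0.44 ± 0.25, Aurka at 0.57 ± 0.41 and Cdc25c at 2.93 ± 1.62. Uhrf1 was at 0.42 without WT-C, Cdk1 and Aurka at 0.29 and 0.30 without 5G2del-A, Aurka at 0.36 without WT-D, and Cdc25c at 1.15 without WT-B. The G2/M call was lost without each of the 5G2del-A, 5G2del-C, WT-B, WT-C and WT-D libraries in turn (camera adjusted p from 0.122 to 0.850).

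Transcripts of mature blood cells varied from library to library. Mature neutrophil and monocyte genes were higher in 13 of 14 members (median 1.97; camera adjusted p = 0.00199; adjusted p = 0.796 with an estimated correlation), with Lcn2 at 4.34 ± 2.25, Chil3 at 3.60 ± 2.34, Ltf at 3.32 ± 2.14 and Lyz2 at 0.28 ± 0.15. The list's mean was high in 1 library of each group, 4.85 log2 CPM in 5G2del-A and 4.20 in WT-A, against -1.72 to 0.78 in the others. Its call was lost without 5G2del-A (camera adjusted p = 0.524; Lcn2 2.44, Chil3 1.44, Ltf 1.53) and without WT-B (0.130; Ltf 1.94), and single values also moved without WT-A (Lcn2 6.59, Chil3 5.58, Ltf 5.37) and WT-D (Chil3 1.71). Erythroid genes were lower in 20 of 23 members (median -0.65; camera adjusted p = 0.0125; adjusted p = 0.797 with an estimated correlation), with the membrane proteins Slc4a1 at -2.88 ± 1.69 and Sptb at -2.21 ± 1.40, and Hemgn the other way at 0.57 ± 0.27. Sptb was at -0.36 without 5G2del-C and -3.79 without 5G2del-A, and Slc4a1 at -4.66 without 5G2del-A. Their means ran from 0.15 to 2.77 log2 CPM in 5G2del and from 0.76 to 3.49 in WT, and the call was lost without 5G2del-B (0.0632), 5G2del-C (0.458), WT-A (0.522) or WT-B (0.360).

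**Figure D3:**
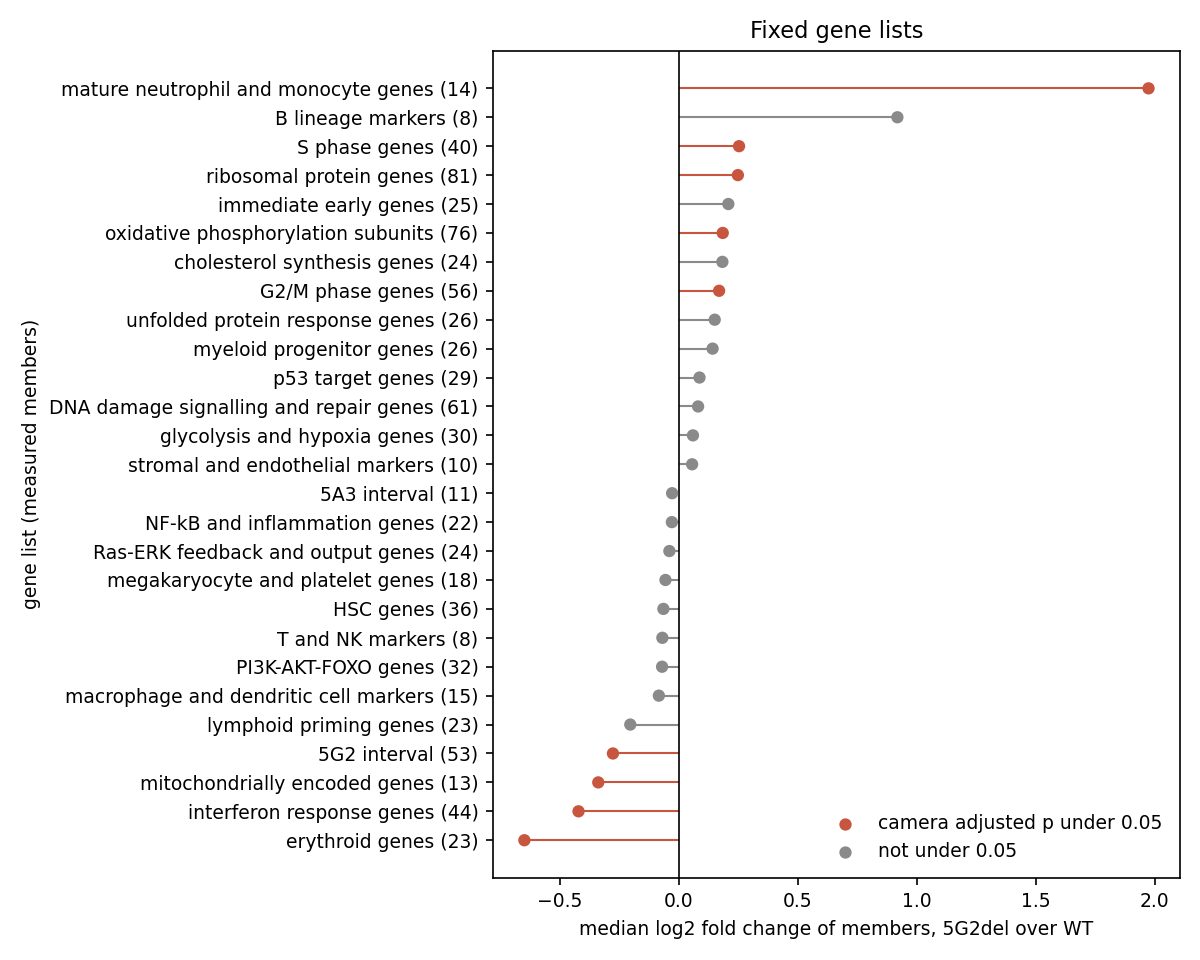
Median log2 fold change of 5G2del over WT of the measured members of each tested list, with their number in brackets; red, camera adjusted p under 0.05 at the preset correlation; grey, not under 0.05. The neutrophil and monocyte list lies farthest right at 1.97 and the erythroid list farthest left at -0.65.

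Stem and progenitor lists did not pass. HSC genes had 24 of 36 members lower (median -0.06; camera adjusted p = 0.272), with Ctnnal1 at 0.84 ± 0.33 and the transporter Abcg2 at -0.44 ± 0.18. Lymphoid priming genes had a median of -0.20 (adjusted p = 0.190 in camera), with Cd79b at 0.56 ± 0.27 and Tcf4 at -0.37 ± 0.19, and myeloid progenitor genes of 0.14 (adjusted p = 0.222), with Nkg7 at 1.16 ± 0.49 (0.63 without WT-B) and Ly86 at -3.22 ± 1.27 (-2.03 without 5G2del-C). Megakaryocyte and platelet genes split 9 higher and 9 lower (median -0.06, mean 0.21, camera adjusted p = 0.726). Adjusted over the list alone, 1 of them passed: Treml1, a platelet receptor, rose by that adjustment, with a log2 fold change of 5.71 ± 1.38 from a WT level near 0 counts, beside Itga2b at 0.93 ± 0.40.

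Markers of other cell types gave no passing list. B lineage markers were higher in 6 of 8 members (median 0.92; camera adjusted p = 0.0681), with the kappa light chain gene Igkc at 6.83 ± 2.07. T and NK markers had a median of -0.07 (adjusted p = 0.680 in camera), with Il2rb at -4.02 ± 1.46 and Lck at -0.50 ± 0.26. Macrophage and dendritic cell markers had -0.08 (adjusted p = 0.561), with Cd163 at -1.14 ± 0.54 and Mrc1 at -1.41 ± 0.75. Stromal and endothelial markers had 0.06 with a mean of 0.14 and a camera direction the other way (adjusted p = 0.912), with Pdgfrb at 1.11 ± 0.77 (0.19 without WT-B) and Sparc at -1.33 ± 0.80 (-0.57 without 5G2del-A, -0.88 without WT-B). Mast cell and basophil markers, with 3 measured genes and a median of 1.18, and sex-linked genes, with 2 and a median of 0.00, were too few for a set test.

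Signalling, stress and metabolic lists did not pass either. Ras-ERK feedback and output genes had 14 of 24 members lower (median -0.04; camera adjusted p = 0.208). Adjusted over the list alone 1 of them passed: Dusp5, the nuclear ERK phosphatase, fell by that adjustment, with a log2 fold change of -1.22 ± 0.27, and Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, had -0.85 ± 0.29. PI3K-AKT-FOXO genes had a median of -0.07 (adjusted p = 0.222 in camera), with Bcl6 at -1.21 ± 0.47 (-0.54 without 5G2del-B) and Pik3r2 at 0.56 ± 0.28. NF-kB and inflammation genes had -0.03 (adjusted p = 0.904), with Nfkb2 at 0.80 ± 0.33 and Tnfaip2 at -0.87 ± 0.49 (-0.54 without WT-A). Immediate early genes had 0.21 (adjusted p = 0.190), with Jun at 0.52 ± 0.25 (0.32 without 5G2del-C) and Hspa1b at 2.42 ± 1.34 (1.38 without 5G2del-B, 1.08 without WT-C).

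For p53 target genes the median was 0.09 and the camera direction the other way (adjusted p = 0.912), with Tap1 at -0.44 ± 0.18 (-0.26 without 5G2del-B) and Zmat3 at 0.52 ± 0.27. DNA damage signalling and repair genes had 40 of 61 members higher (median 0.08; camera adjusted p = 0.222), with Apex1 at 0.48 ± 0.20. Cholesterol synthesis genes had a median of 0.18 (adjusted p = 0.112 in camera), with Fdps at 0.94 ± 0.27 and Mvd at 1.43 ± 0.60 (0.84 without 5G2del-A). Glycolysis and hypoxia genes had 0.06 (adjusted p = 0.0906), with Pgam1 and Tpi1 both at 0.49 (SE 0.18 and 0.19; Pgam1 0.30 without 5G2del-B), and unfolded protein response genes 0.15 (adjusted p = 0.0800), with the chaperones Hspa5 at 0.44 ± 0.20 and Calr at 0.35 ± 0.20 (0.20 without 5G2del-A, 0.55 without 5G2del-C).

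Immunoglobulin transcripts, named after their values were seen, were among the single genes with small p-values. A kappa light chain variable gene (identifier ENSMUSG00000076523, mm10 chromosome 6, 68437440 to 68437925) had the lowest p of all genes in limma-trend (limma adjusted p = 0.151). It had 0 expected counts in all 4 WT libraries and 27.4 ± 34.8 CPM in 5G2del (SD, n = 3). This mean was at least 319-fold higher than the highest WT floor of 3 counts per library. That mean rests on 5G2del-A: the bound was 88.3-fold without it and 23.0-fold for the lowest 5G2del library. Igkv14-126 had a log2 fold change of 6.87 ± 1.34, Ighv11-2 of 6.34 ± 1.20, and Jchain, the joining chain of secreted IgM and IgA, of 4.53 ± 1.29. In the authors' voom fit the first-named kappa variable gene did not lead, with a limma unadjusted p of 0.0394. There Ighv11-2 had 0.0132, Jchain 0.0204 and Igkv14-126 0.000817. The agouti gene a, a pigmentation signal (mm10 chromosome 2, 154791402 to 155051012), was likewise named after its values were seen. It had 109, 62 and 104 expected counts in the 5G2del libraries and 0, 0, 0 and 5 in WT (log2 fold change 6.70 ± 1.35, limma adjusted p = 0.874). Its annotated span overlaps that of Raly (154791096 to 154867261) on the same strand, so reads in the overlap cannot be told apart. Raly itself had a log2 fold change of 0.09 ± 0.18.

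**Figure D4:**
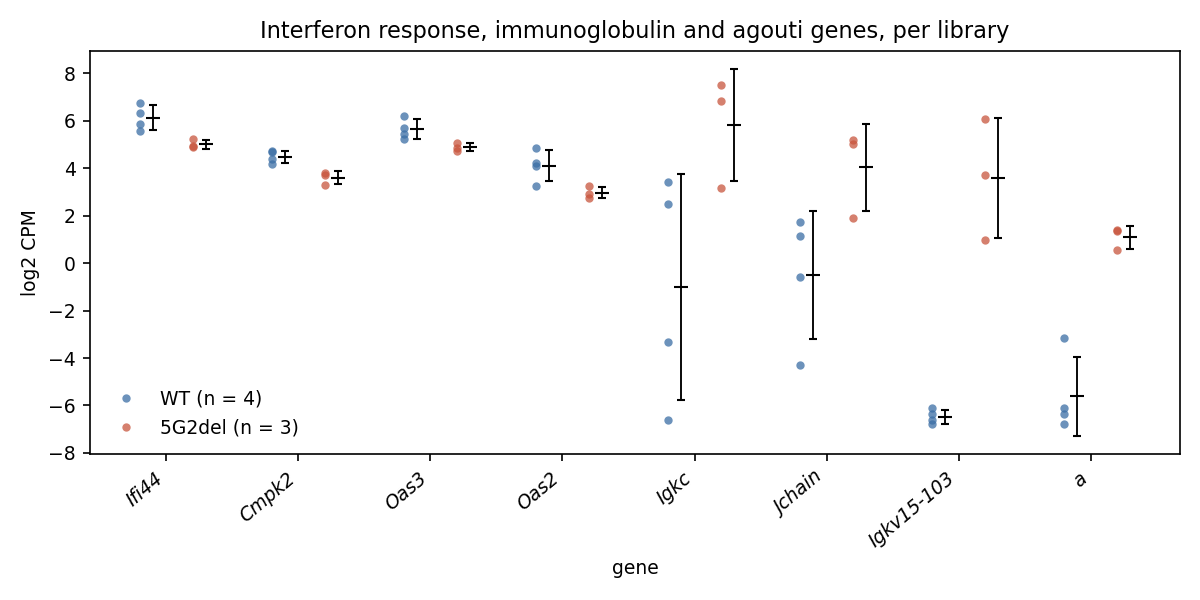
Log2 CPM per library of 4 interferon response genes, 3 immunoglobulin-related genes, the last of them the kappa variable gene without WT counts, and the agouti gene (blue, WT, n = 4; red, 5G2del, n = 3; bars, mean ± SD). That variable gene lies at 0 counts in every WT library, and the 3 5G2del libraries spread around 3.60 log2 CPM with an SD of 2.54.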

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

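The tests of a single immunoglobulin source and of fewer macrophage or dendritic cells were chosen only after their results were seen, as was the count of splits for genes past the threshold. In groups of 4 libraries, 163 values were searched for 1 library far from the other 3 by a gap test, which flags about 1 in 20 groups by chance; 11 stood out where 8.15 were expected. WT-B had 1104 genes at 0 counts, against 105 to 226 in the other WT libraries. In the same library the mean of T and NK markers was -2.34 log2 CPM (others -0.17 to 0.16), that of Ras-ERK genes 2.90 (3.47 to 3.55), Pdgfrb 0.20 (3.58 to 4.25), Tcf4 6.50 (6.98 to 7.05), Ighv7-1 0.25 (-6.80 to -6.12) and Trim56 6.14 (5.84 to 5.88). In WT-C the sex-linked list, which is Xist and Tsix, had a mean of 6.39 (5.11 to 5.29), mt-Rnr1 was at 17.05 (16.51 to 16.60) and Gnb2 at 4.77 (5.20 to 5.29). Prim1 was at 5.13 in WT-D (4.82 to 4.87).

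Immunoglobulin transcripts were the first pattern weighed. A single source behind all immunoglobulin RNA would hold its transcripts in 1 ratio: at the lowest ratio to Igkc in 5G2del (0.115), the kappa variable gene would have 69.5 counts in WT-A and 26.5 in WT-B, where it had 0. Of 1296 genes at the same predicted count, 0.309% were at 0 in WT-A, and another of the 7 measured variable genes, Ighv1-77, had 42 and 51 counts in WT-C and WT-D beside 3 and 0 of Igkc, which argues against a single source and leaves open 1 that adds to others. Cells of the B or plasma lineage, a candidate source that the CD150-negative gate would not remove, stay open: 6 measured B and plasma markers other than immunoglobulin genes had a median log2 fold change of -0.078 with a spread of 0.47, 3 of them higher, and other splits of the libraries reached 1.27. Igkc itself ran from 380 to 7643 expected counts in 5G2del and from 0 to 604 in WT, Ighm from 1328 to 13993 and from 670 to 5856, and whether the deletion plays a part was not tested.

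The agouti gene was the second pattern. It is located on chromosome 2, away from the deletion, and a linked stretch from another mouse strain could bring an expressed allele into the 5G2del line. Of 138 measured genes within 5 Mb of it, 2 had an unadjusted p under 0.05, 0.369 of the share elsewhere (Fisher's exact test, two-sided, p = 0.182). That stretch and the genotype cannot be told apart on this count, since linked alleles need not differ in expression. An agouti coat-colour marker carried by a targeting vector is another candidate explanation, untested here because gene totals do not show which exons were read. Reads from the span shared with Raly could not be separated for the same reason.

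The lower interferon list was the third. A difference carried by 1 WT library is argued against, since without each WT library in turn the median stayed at or below -0.32 (-0.42 with all). WT-C and WT-D were highest, with list means of 5.09 and 4.94 log2 CPM. Leaving out 1 at a time keeps the other, so a difference carried by both stays open. With the mean of ribosomal protein transcripts as a covariate, the median was -0.56 and so did not shrink. That mean mostly set WT-A (8.24 log2 CPM) apart from the other libraries (9.05 to 9.60), and without WT-A the median was -0.53. The covariate thus stood largely for 1 library, so a library-wide axis stays open. Fewer macrophage or dendritic cells stay open, with a median of -0.092 over 14 markers outside the list. Chance in the grouping could not be excluded, because 6 of 35 splits of the libraries gave a median as far from 0 (0.42 in size, highest other 0.53).

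For the other results the same splits were counted. Genes past the threshold numbered 0 in the real split and up to 3 in others; any of the 35 splits gives at least 0, so this count decides nothing. The 656 genes with an unadjusted p under 0.05 were matched or passed in 23 of 35 splits (highest other 1468), and 9 passing lists in 23 of 35 (highest other 17). Chance was not excluded for these 2 counts. The median of the 5G2 interval list, 0.28 in size, was reached in 3 of 35 splits (highest other 0.29). Among runs of 20 neighbouring expressed genes, the strongest, Mdh2 to Slc12a9 on chromosome 5, had a mean log2 fold change 0.65 in size. Of the 35 splits 1, the real one, gave a run as strong (highest other 0.60). A first rank is the most that 35 splits can show, and the next value was close. On this count alone chance was therefore made less likely for this run but was not excluded. The count takes no account of position, and the run overlaps the genes of the 5G2 interval list, fixed beforehand. Members of that list lower at an unadjusted limma p under 0.05, a count chosen after the data were seen, numbered 9 in the real split. No other split gave more than 5.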

How the results depend on the processing

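The authors' voom fit, array weights, rescaling to equal totals, the removal of low list members, permutation of list medians, an unadjusted threshold for the interval, the stretch from Rasa4 to Zan and the removal of 5G2del-A with WT-A were chosen only after the data were seen. No paired analysis was possible because the columns carry no replicate numbers. A run without the authors' filter could not be made on genes filtered before deposit, and count tools lacked whole counts. Another offset could have been applied to the recovered expected counts but was not run. How far fold changes of genes with few counts depend on the offset was therefore not tested. Other ranking statistics were not run. Of comparisons between a setting and the reported fit, 1653 of single genes and 443 of lists kept direction and side of the threshold; 31 of lists gained a call, 48 lost it and 38 turned. The median of all genes lay between 0.00 and 0.05 in every refit. Genes with an unadjusted p under 0.05 were 42.8% higher in limma-trend, 55.5% in the authors' fit and 33.0% to 52.6% over the leave-outs. Low genes were found less often: simulated changes of 2 on the log2 scale were found for 71.9% of genes with a mean log2 CPM over 2 and 45.0% of all. Depth itself was not varied. The cause was not tested for any difference below, except that leave-outs have fewer samples and filters fewer genes.

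Genes past the threshold numbered 0 to 1 over the leave-outs (1 without 5G2del-C) and 1 without the trend. At an unadjusted p under 0.01 there were 90, a count with no correction for the 16760 genes tested. Genes with an unadjusted p under 0.05 numbered 464 to 980 over the leave-outs (980 without WT-B) and 1110 with array weights, which gave WT-B the lowest weight (0.34). Chance gives 838 among 16760 genes. Above the median of mean expression there were 327 of 8380. Interval members lower and past the threshold over all genes numbered 0, and 9 were lower at an unadjusted p under 0.05. Adjusted over the list alone, 1 to 3 passed over the leave-outs (1 without 5G2del-A, 5G2del-B, WT-B or WT-D, 3 without 5G2del-C), 0 without the trend, 5 with quantile normalization, 5 above the median expression, 4 among protein-coding genes and 8 with array weights. The interval median was -0.36 to -0.18 over the leave-outs and -0.32 with quantile normalization. The interval list's adjusted p was 1.27e-06 to 0.00117 over the leave-outs, 0.660 with an estimated correlation, 0.580 in fry and 0.836 by permutation. That of the interferon list was 9.50e-23 to 6.38e-08, then 0.660, 0.836 and 0.836, and its median -0.63 to -0.32. Its members lower at an unadjusted p under 0.05 numbered 5 to 19 over the leave-outs (8 without 5G2del-A, 5 without 5G2del-B, 8 without WT-C, 7 without WT-D), 6 without the trend and 27 with array weights. From Rasa4 to Zan, 96.4% to 100% of genes were lower over the leave-outs (96.4% without 5G2del-A or WT-B).

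Passing lists numbered 8 to 12 over the leave-outs, 14 without 5G2del-A and WT-A, and 0 with an estimated correlation, in fry and by permutation. List directions turned as follows, with adjusted p. The p53 list: 0.971 without the trend, 0.805 without 5G2del-A and WT-A, 0.994 in fry, 0.696 without shared genes, 0.836 by permutation and 0.307 to 0.949 over the leave-outs (5G2del-A, 5G2del-B, WT-C, WT-D turned it). The 5A3 list: 0.980 with quantile normalization, 0.833 without 5G2del-A and WT-A, 0.994 in fry and 0.482 to 0.998 (5G2del-B, WT-A, WT-B). Stromal markers: 0.643 without 5G2del-A and WT-A, 0.994 in fry, 0.914 by permutation and 0.307 to 0.925 (5G2del-A, 5G2del-B, WT-C). Megakaryocyte genes: 0.671 above the median expression, 0.911 without low members, 0.836 by permutation and 0.206 to 0.949 (5G2del-C). Macrophage markers: 0.949 above the median expression. Immediate early genes: 0.170 with array weights and 0.000139 to 0.546 (5G2del-C, WT-B). In leave-outs alone turned HSC genes (0.0485 to 0.995; WT-B), myeloid progenitor genes (0.00131 to 0.995; 5G2del-A, WT-B), T and NK markers (0.307 to 0.901; 5G2del-B), NF-kB genes (0.0971 to 0.922; 5G2del-B, WT-C), PI3K genes (0.00528 to 0.579; 5G2del-B), cholesterol genes (0.000825 to 0.728; WT-C) and ribosomal protein genes (3.29e-16 to 0.438; WT-A). Calls were gained by lymphoid priming genes without 5G2del-A or WT-B, myeloid progenitor genes and B lineage markers without 5G2del-B or WT-A, PI3K genes without 5G2del-A, immediate early genes without 5G2del-B, WT-C or WT-D, cholesterol genes without 5G2del-C, WT-A or WT-B, glycolysis genes without 5G2del-C or WT-B, unfolded protein response genes without WT-A or WT-B, and HSC and DNA damage genes without WT-A.

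Genes that turned, in log2 fold change, were Ywhag (-0.012 with quantile normalization, -0.13 to 0.12 over the leave-outs; 5G2del-B, 5G2del-C, WT-C, WT-D), Gnb2 (-0.084 without 5G2del-A and WT-A, -0.14 to 0.15; 5G2del-A, WT-C), Trip6 (0.0031 without 5G2del-A and WT-A, -0.52 to 0.19; 5G2del-A), Dtx2 (-0.039 to 0.33; 5G2del-A) and Zan (-0.87 to 0.0036; WT-B).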

Other observations

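Replication-dependent histone genes, a group outside the fixed lists that was picked out after the values were seen, were higher in 5G2del in 55 of 61 measured members, 14 of them with an unadjusted p under 0.05. Among linker histones 5 of 6 H1 genes were higher, with Hist1h1c at 0.83 ± 0.27, Hist1h1b at 0.70 ± 0.23, Hist1h1d at 0.65 ± 0.20 and Hist1h1e at 0.60 ± 0.17 (log2 fold change ± SE), and a median of 0.62. It was asked whether core histone genes may share the difference. Of the other 55 histone genes 50 were higher, with a median of 0.63, so they shared the direction and size of the H1 genes. That median was reached in 3 of 35 splits (highest other 0.68), and the H1 median in 1, the real one (highest other 0.61). Chance in the grouping therefore stays open for the histone genes. The next strongest run of neighbours after the chromosome 5 stretch lay in the histone cluster of chromosome 13, from Hist1h2bl to Hist1h4d, with a mean of 0.46. Polyadenylated and other histone transcripts were not separated by the amplification, and members share sequence, so single values are uncertain.

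Some other single genes with small p-values were named after their values were seen. Tnip3, an inhibitor of NF-kB signalling, had a log2 fold change of -1.19 ± 0.22, Vldlr, a lipoprotein receptor, of -0.80 ± 0.20, and Mmrn1, a platelet and endothelial protein, of 0.79 ± 0.16, each without overlap of the groups and each short of the adjusted threshold in limma. Sfrp5, a secreted Wnt inhibitor, had 0 expected counts in every WT library and 0.380 ± 0.104 CPM in 5G2del (SD, n = 3), at least 4.42-fold higher than the WT floor of 3 counts per library.

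It was also asked whether chromosome 5 genes outside the stretch could differ more often than those of other autosomes, as linked variants might make them. On chromosome 5, 48 of 1147 genes had an unadjusted p under 0.05, 4.18% against 3.83% elsewhere (Fisher's exact test, two-sided, p = 0.524; odds ratio 1.10, 95% interval 0.795 to 1.49). The interval includes an odds ratio of 1 and an increase, so the question stays open. Abcf2 (0.90 ± 0.19) and Alox5ap (0.55 ± 0.15), picked from the 48 genes after their values were seen, were higher in 5G2del without overlap of the groups. The others of the 48 are not listed here.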
